A study of Nannochloropsis oceanica with 6 samples.

How the data were processed

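Messenger RNA was sequenced from 6 libraries of Nannochloropsis oceanica CCMP1779, a unicellular marine alga, in 3 groups of 2 libraries. All cultures had grown in cycles of 12 h light (30 µmol s−1 m−2) and 12 h dark at 22 °C. They were transferred at zeitgeber time 12 h, counted from lights on, and held in darkness for 36 h. All responses were thus measured at the same time of the cycle. Per the labels' protocols, 1 group then received 5 min of blue light, another 5 min of red light, both at 20 µmol s−1 m−2, and the third stayed dark. Every culture stood in darkness for a further 15 min before harvest, and polyadenylated RNA was made into strand-specific libraries. The labels number the replicates but do not say that they came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

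FastQC, TopHat, Cufflinks, Cuffnorm and Cuffdiff are named, without roles or versions, per the submitters' processing notes. Aligner settings, filters and the strand setting of the counting are not given in the sources used here. FPKM values (by the usual definition fragments scaled to transcript length and to the fragments of the library) were deposited for each library, per the file headers. TPM values were deposited beside them, per the file headers, and equal the FPKM of the same library multiplied by 1 constant. The FPKM columns sum to between 588091.6 and 767746.9 per library, so the units scale the libraries differently. Whether Cuffnorm also scaled the libraries against each other is not given in the sources used here. Log2 fold changes of each pulse against dark were deposited by the authors, per the file headers, and they equalled the log2 ratio of mean FPKM within 0.01 in 100% of tested models with finite values. The authors' p-values and q-values of the same comparisons were deposited too, per the file headers. Gene models are those of the Nanoce1779_2 annotation as named in the deposited table, which also gives scaffold coordinates and functional descriptions. Models are named here by description and protein identifier.

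Values were present for 10635 of 10641 models. The 9087 models with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1), so a fold change understates the change of low models. The test was limma 3.58.1 in R 4.3.3 (linear model on all 6 libraries, 3 residual degrees of freedom, moderated variance with a trend, two-sided), with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The comparisons were blue against dark, red against dark, and blue against red as the direct test of a difference between pulses. On simulated data for blue against dark over 9087 models, the procedure recovered 64% of changes of 0.5 log2 and 98% of changes of 1 log2, with 14 false calls among 195. The simulation changed 50 models at each size, in blue only, with independent noise of the fitted spread. In the data 76.1% of models were called in blue against dark, so these rates need not carry over.

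The files hold no counts. The steps between low FPKM values gave the relative number of fragments behind 1 FPKM, with dark replicate 1 set to 1. This was 1.089 for dark replicate 2, 1.663 and 1.196 for blue replicates 1 and 2, and 1.69 and 1.328 for red replicates 1 and 2. From 105 low models on a common line of fragments against length, 1 FPKM was estimated at 16.9 and 18.4 fragments per kb in dark, 28.0 and 20.2 in blue, and 28.5 and 22.4 in red replicates 1 and 2. Total fragments per library were not derived. Whole fragments were recovered for low models only, so no count test was run. Of 205 low models checked at 3 to 25 fragments, 104 had values within 0.15 of a whole number in every library. Over these 104 models, replicates differed no more than counting noise, but the check had little power. Counting noise is large at so few fragments, and only models within 3 to 25 fragments in every library were kept. The chi-square per degree of freedom was 0.834 in dark, 0.945 in blue and 0.927 in red. Over models with more than 200 fragments, estimated from the genomic span and so too high where a model has introns, the median chi-square was 1.319 in dark, 7.724 in blue and 4.271 in red, against 0.455 by chance. It rose with the level, in dark from 0.54 at 20 to 100 fragments to 2.73 at 2000 or more, a check added after seeing the data. No pair was treated as 1 library deposited a second time. The check cannot exclude this, because differences in the handling of 1 RNA could also add spread at high levels. In dark the excess was smallest.

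Before the data were examined, 23 gene lists were fixed as word patterns on the descriptions. Of these, 22 had at least 5 tested members, and the list of organelle-encoded genes, meant as a check of RNA quality, matched 0 models. Lists were tested with limma's camera (preset correlation 0.01), with an estimated correlation and with fry beside it, and adjusted over the 22 lists within a comparison. Camera compares the changes of a list with those of the other tested models. Its direction is therefore relative and can differ in sign from the list's own median or mean. The genes named were also set by a rule fixed beforehand. For each pulse against dark these were the 10 largest rises and 10 largest falls among called models with a functional description whose replicates did not overlap those of the other group, and for blue against red the 5 largest each way. To these were added the 4 members of each list with the smallest p in blue against dark, and any member of the photoreceptor and the desaturase lists. Genes named outside this rule are said to be so.

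Of the tested models, 3433 (37.8%) overlap another model, 1938 of them on the opposite strand only. Because the strand setting of the counting is not given, values of overlapping models are uncertain, and reads shared between members of a gene family were not tested. Alternatives fixed beforehand were TPM, other pseudocounts and filters, quantile normalization, median centring, replicate blocks, other variance settings, other thresholds and the removal of each library. Models without overlap, lists narrowed to remove members matched by unrelated words, and a different dark library behind each pulse were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.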

Results

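The study compared Nannochloropsis oceanica cells that had received a short pulse of blue or red light after prolonged darkness with cells left in the dark. Each group held 2 libraries. The FPKM sums were 767192.8 and 767746.9 in dark, 624861.3 and 662228.8 in blue, and 588091.6 and 615972.2 in red libraries. The 100 most abundant models took 25.9% and 25.8% of the dark totals, and between 18.1% and 18.9% of the totals of the pulsed libraries. On the first principal component, which held 76.7% of the variance, the red libraries (−1.88 and 1.60) lay between the dark (−51.8 and −50.9) and the blue libraries (49.5 and 53.5). Replicates differed by a median absolute log2 value of 0.072 in dark, 0.143 in blue and 0.112 in red.

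The first comparison asked which transcripts differed 15 min after a blue pulse. The largest rise was that of a T-complex protein 11 domain protein (667321; scaffold 1, 399006 to 402818), from 5.09 ± 0.47 FPKM in dark to 1833 ± 46.5 FPKM in blue libraries (SD, n = 2; log2 change 8.24, SE 0.095, adjusted p = 1.75e-10). Aureochrome 4 (622551; scaffold 3, 1242681 to 1243694), a member of the blue light receptor family of stramenopile algae that joins a bZIP and a LOV domain, rose from 4.97 ± 0.22 to 1484 ± 263 FPKM (SD, n = 2; log2 change 7.95, SE 0.15, adjusted p = 1.49e-09). Desaturases of fatty acids followed, with 591536 at 1.82 in dark and 655 FPKM in blue, delta-6 desaturase (606752) at 1.35 and 296.5 FPKM, and desaturase 639463 at 3.93 and 519 FPKM. A GTP-binding elongation factor (572801) rose from 7.59 to 976 FPKM and an NAD-dependent epimerase (576408) from 17.6 to 1698 FPKM. The remaining named rises were a Kua-ubiquitin conjugating enzyme hybrid (577358, log2 change 6.11), cryptochrome DASH (622582, 6.09) and a mitochondrial carrier (588372, 5.74). Models 591536, 606752, 577358 and 622582 overlap another model.

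Among described models without overlap, the largest fall was that of a biopterin-dependent aromatic amino acid hydroxylase (585185; scaffold 7, 1093170 to 1095652), from 605 ± 38.1 to 29.6 ± 0.37 FPKM (SD, n = 2; log2 change −4.30, SE 0.081, adjusted p = 1.42e-09). Its neighbour 585179, annotated with the NAD-binding domain of 6-phosphogluconate dehydrogenase, fell from 664 to 48.7 FPKM. Methionine synthase of the cobalamin-independent type (616145) fell from 212.5 to 16.6 FPKM, a SANT/Myb domain protein (523144) from 124 to 9.37 FPKM, and a protein annotated as nuclear control of ATP synthase (603379) from 146 to 11.3 FPKM. The other named falls were overlapping models, among them a KIF-1 binding protein (291741, 100.2 to 2.80 FPKM) and a C2 domain protein (588568, 57.5 to 3.36 FPKM). A Ysc84 domain model (573276) at 40.2 FPKM in dark was listed at 1.94e-07 FPKM in blue.

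Of 13 tested photoreceptor and photolyase models, 5 rose and 6 fell after blue light (6 rose and 6 fell when adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.945). As a background for this and the later list counts, 3626 of all 9087 tested models rose and 3292 fell after blue light. With TPM 6 of 14 members of the photoreceptor list rose and 5 fell. Without the members matched through the word rhodopsin, a narrowing made after seeing the data, 4 of 6 rose and 2 fell (median log2 change 1.56, adjusted p = 0.298). Besides aureochrome 4 and cryptochrome DASH (0.90 to 129 FPKM), a photolyase or cryptochrome model (571816) rose from 14.6 to 58.2 FPKM and a photolyase (529956) from 8.93 to 21.7 FPKM. Aureochrome 1 (550823) fell from 787 ± 33.8 to 267 ± 3.87 FPKM and aureochrome 3 (582424, overlapping) from 751 ± 37.1 to 435 ± 15.3 FPKM (SD, n = 2; log2 changes −1.55 and −0.79). Among the rest, 5 models were transporters of the organic solute family matched through the word rhodopsin.

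**Figure D1:**
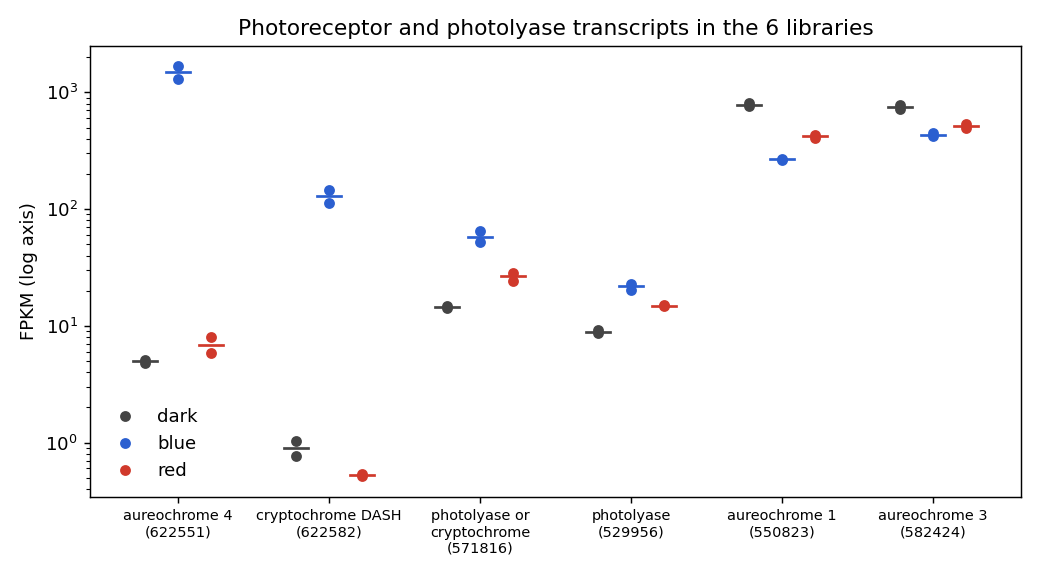
FPKM on a log axis of 6 photoreceptor and photolyase models, with 1 point per library and a bar at the group mean. Aureochrome 4 stands at 1484 FPKM in blue libraries against 4.97 in dark and 6.91 in red, and aureochrome 1 is highest in dark.

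Fatty acid desaturases and elongases rose together after blue light, with 23 of 37 tested members up and 8 down, the same counts when adjusted over the list alone (camera adjusted p = 0.00527; adjusted p = 0.778 with an estimated correlation). Beyond the members above, a long chain fatty acid elongase (391778) rose from 20.7 to 493 FPKM and stearoyl-CoA desaturase (593563) from 50.1 to 790 FPKM. A fatty acid elongase (572755) went the other way, from 104 to 8.08 FPKM. The list also took carotene, phytoene and sterol desaturases; without these, 15 of 26 members rose and 7 fell (adjusted p = 0.0323; adjusted p = 0.778 with an estimated correlation). Carotenoid genes rose in 12 of 19 cases and fell in 1 (adjusted p = 0.0102; adjusted p = 0.778 with an estimated correlation), the same counts when adjusted over the list alone, including chloroplast phytoene desaturase (593703), an early enzyme of carotenoid synthesis, from 40.1 to 352 FPKM.

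Ribosomal proteins formed the list with the smallest p, with 128 of 166 members up and 19 down, also when adjusted over the list alone (median log2 change 1.31, adjusted p = 8.7e-11; adjusted p = 0.778 with an estimated correlation). Examples were a ribosomal protein of the L7Ae family (251469, overlapping, 9.73 to 168 FPKM) and one of the L6 family (646820, 13.8 to 155.5 FPKM). Ribosome biogenesis genes rose in 75 of 115 cases and fell in 19, or 76 and 21 adjusted over the list alone (adjusted p = 0.000372; adjusted p = 0.778 with an estimated correlation), with Urb2/Npa2 (577545) up from 9.64 to 206 FPKM and a Utp23-like protein (130052) down from 35.0 to 1.04 FPKM, both of them overlapping models. Glycolysis genes rose in 26 of 38 cases and fell in 9, or 27 and 9 adjusted over the list alone (adjusted p = 0.00527; adjusted p = 0.837 with an estimated correlation). Phosphoglycerate kinase (543791) went from 2.54 to 89.7 FPKM and pyruvate kinase (615861) from 14.0 to 120.5 FPKM. In nitrogen assimilation, 16 of 21 members rose and 3 fell, or 16 and 4 adjusted over the list alone (adjusted p = 0.00527; adjusted p = 0.778 with an estimated correlation), among them nitrate reductase (590448, 0.73 to 64.0 FPKM) and a nitrite or sulphite reductase (600410, 13.1 to 272 FPKM).

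Lipases and genes of fatty acid beta oxidation fell in 44 of 74 cases and rose in 15, the same counts when adjusted over the list alone (adjusted p = 0.00527; adjusted p = 0.778 with an estimated correlation). With TPM 36 fell and 23 rose (camera adjusted p = 0.011), and with median centring 53 fell and 11 rose (camera adjusted p = 0.00553). Of the members with the smallest p, a short-chain dehydrogenase (591729) fell from 74.3 to 8.42 FPKM, whereas the lipid droplet surface protein (591558, overlapping), a structural protein of oil bodies, rose from 92.9 to 635 FPKM. Heat shock proteins and chaperones fell in 67 of 129 cases and rose in 43, or 68 and 43 adjusted over the list alone (adjusted p = 0.0453; adjusted p = 0.778 with an estimated correlation). An HSP20-like chaperone (607932, overlapping) fell from 228 to 31.6 FPKM, while a protein with SANT/Myb domains that the list also took (243818) rose from 98.2 to 2412 FPKM. The call of the heat shock list was lost with quantile normalization (adjusted p = 0.111) and with median centring (adjusted p = 0.0779). With TPM 56 of 131 members fell and 51 rose, with a median log2 change of −0.116 (camera adjusted p = 0.0203).

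The other lists did not pass after blue light. Light harvesting genes, a gene family in which sharing of reads between members was not tested, rose in 9 of 27 cases and fell in 13 (adjusted p = 0.787), with 581022 up from 14.3 to 268.5 FPKM and 643295 down from 85.2 to 33.7 FPKM. Chlorophyll synthesis rose in 9 of 15 cases and fell in 3 (adjusted p = 0.0565), with glutamyl-tRNA reductase (589090), the committed step of the pathway, up from 76.1 to 275 FPKM. The chlorophyll list passed without red replicate 1 (adjusted p = 0.0403) and without red replicate 2 (adjusted p = 0.0402), which enter through the shared variance. Carbon fixation genes rose in 20 of 38 and fell in 14 cases (adjusted p = 0.449), photosystem and electron transport genes in 21 and 13 of 40 (adjusted p = 0.61), and fatty acid synthesis and glycerolipid genes in 49 and 42 of 110 (adjusted p = 0.945). Transcription factors rose in 56 and fell in 51 of 145 cases (adjusted p = 0.945), signalling kinases and phosphatases in 81 and 86 of 227 (adjusted p = 0.895), proteasome and ubiquitin genes in 75 and 114 of 238 (adjusted p = 0.114), and cell cycle genes in 27 and 41 of 95 (adjusted p = 0.114). The counts were 39 and 46 of 115 for oxidative stress (adjusted p = 0.799), 46 and 40 of 109 for mitochondrial respiration (adjusted p = 0.945), 22 and 21 of 52 for DNA repair (adjusted p = 0.945), and 8 and 6 of 19 for autophagy (adjusted p = 0.864). The balance of most of these lists turned with the scaling. With TPM 102 of 239 proteasome and ubiquitin genes rose and 80 fell, 104 and 65 of 233 kinases and phosphatases, 59 and 34 of 115 oxidative stress genes, and 14 and 11 of 27 light harvesting genes. With median centring 14 photosystem genes rose and 18 fell, 16 and 17 carbon fixation genes, 34 and 54 of fatty acid synthesis, 38 and 70 transcription factors, 32 and 51 of mitochondrial respiration, 15 and 25 of DNA repair and 4 and 8 of autophagy. For light harvesting, transcription factors, oxidative stress, mitochondrial respiration, DNA repair and the kinases, camera's direction was down while the mean log2 change was above 0. That direction is set against the other models and does not by itself mean a fall of the list. The median was below 0 for light harvesting (−0.001) and the kinases (−0.039). The median of light harvesting was 0.252 with TPM and −0.267 with median centring. With red light the median, mean and test also differed in sign for photosystems (−0.072, 0.086 and down), transcription factors (0.043, −0.002 and down) and photoreceptors (−0.007, 0.059 and up).

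In all, 6918 of 9087 models passed in blue against dark, 3626 higher and 3292 lower (52.4% higher). The split followed the scaling: with TPM 4551 were higher and 2475 lower (64.8%), with quantile normalization 3130 and 3589 (46.6%), and with median centring 2642 and 4301 (38.1%). The median log2 change of all tested models was 0.045 on FPKM, 0.269 on TPM, −0.060 with quantile normalization and −0.22 with median centring. The direction of small changes therefore depended on the scaling. These medians set no bound, because some larger changes turned as well. Desaturase 522533 stood at 0.534 after blue light with quantile normalization and at −0.324 with median centring. At least 8-fold changes were called for 120 rises and 29 falls. In the authors' deposited table, 5392 of the tested models had q under 0.05, and 5373 of these were also called here.

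**Figure D2:**
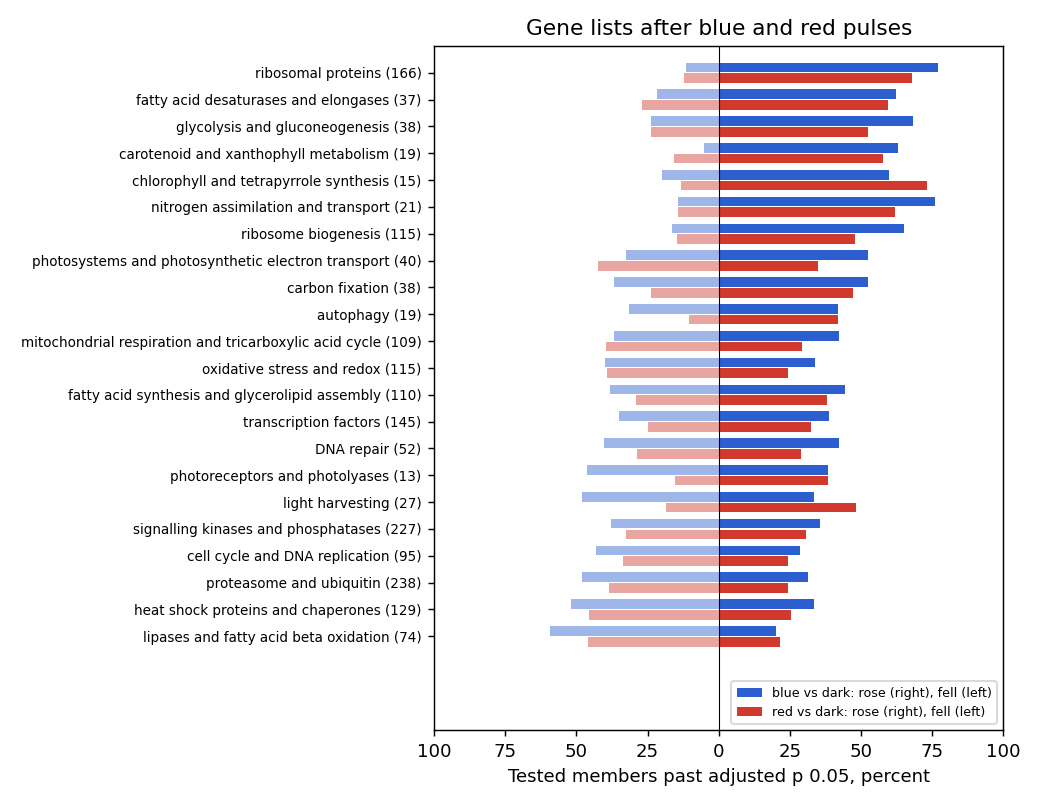
Share of tested members of 22 gene lists (number tested in parentheses) past adjusted p 0.05, rises to the right and falls to the left, for blue against dark and red against dark. Ribosomal proteins rose in 128 of 166 cases after blue and 113 of 166 after red light.

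The second comparison asked the same of the red pulse. The largest rise was that of an Armadillo-type fold protein with a RING finger (611415; scaffold 56, 39271 to 44788), from 7.59 ± 3.51 FPKM in dark to 187 ± 15.3 FPKM in red libraries (SD, n = 2; log2 change 4.51, SE 0.23, adjusted p = 9.42e-07). An elongase of the GNS1/SUR4 family (622402, overlapping) rose from 1.54 to 47.1 FPKM, and a fusion of triosephosphate isomerase and glyceraldehyde-3-phosphate dehydrogenase (623181, overlapping) from 9.99 to 131 FPKM. A second Armadillo-type protein (609232) rose from 14.9 to 156 FPKM, a trigger factor, which is a chaperone of nascent proteins (598404), from 8.38 to 75.0 FPKM, and a mitochondrial carrier (580737, overlapping) from 25.6 to 182.5 FPKM. All of these also rose after blue light.

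Heat shock protein 70 (574559; scaffold 2, 690577 to 694080) fell after red light from 1171 ± 9.21 to 145 ± 22.1 FPKM (SD, n = 2; log2 change −3.01, SE 0.14, adjusted p = 6.47e-07). An AAA ATPase domain protein (597514) fell from 290 to 34.0 FPKM, a TPR repeat protein (609277) from 423 to 42.6 FPKM, a fatty acid elongase (572755) from 104 to 9.91 FPKM, and an actin domain protein (580844) from 16.5 to 1.09 FPKM. An alpha/beta hydrolase (638307, overlapping) went from 30.1 to 2.86 FPKM and a WW domain protein (604308) from 20.1 to 1.61 FPKM. These models fell after blue light as well.

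Heat shock proteins and chaperones fell in 59 of 129 cases and rose in 33 after red light (camera adjusted p = 0.00936, and adjusted p = 0.777 with an estimated correlation). With TPM 45 of 131 fell and 56 rose, with a median of 0.103. Camera's direction stayed down (adjusted p = 0.000897), because the list lay below the other models. The median of all tested models was 0.363 with TPM. Adjusted over the list alone, 60 fell and 34 rose. Here ribosomal proteins rose in 113 of 166 cases and fell in 20 (adjusted p = 1.2e-10; adjusted p = 0.777 with an estimated correlation). Chlorophyll synthesis rose in 11 of 15 cases and fell in 2 (adjusted p = 0.0212; adjusted p = 0.777 with an estimated correlation), with glutamyl-tRNA reductase (589090) up from 76.1 to 172 FPKM. Nitrogen assimilation rose in 13 of 21 cases and fell in 3 (adjusted p = 0.0191; adjusted p = 0.777 with an estimated correlation), with nitrate reductase (590448) up from 0.73 to 7.71 FPKM. Ribosome biogenesis rose in 55 of 115 cases and fell in 17 (adjusted p = 0.0288; adjusted p = 0.777 with an estimated correlation), and was not called without red replicate 2 (adjusted p = 0.0521). The counts of these last 4 lists were the same when adjusted over the list alone. With TPM, chlorophyll synthesis (adjusted p = 0.0656), ribosome biogenesis (adjusted p = 0.0656) and nitrogen assimilation (adjusted p = 0.0942) were no longer called. Quantile normalization lost ribosome biogenesis (adjusted p = 0.1) and added light harvesting (adjusted p = 0.0379 against 0.381) and glycolysis (adjusted p = 0.0148 against 0.0969). Desaturases and elongases rose in 22 and fell in 10 of 37 cases without passing as a list (adjusted p = 0.148). Aureochrome 1 (550823) fell from 787 to 421 FPKM. Aureochrome 3 fell from 751 to 519 FPKM, a log2 change of −0.53 that turned to 0.115 with quantile normalization (adjusted p = 0.174). Aureochrome 4 was at 6.91 ± 1.58 FPKM in red libraries (SD, n = 2; adjusted p = 0.0475), a log2 change of 0.39 whose call was lost without dark replicate 1 (0.354, adjusted p = 0.138), dark replicate 2 (0.43, adjusted p = 0.0761) or red replicate 2 (0.187, adjusted p = 0.345), and with quantile normalization (0.234) and median centring (0.23). It was also lost with a pseudocount of 5 (0.25, adjusted p = 0.12), without a filter on low values (adjusted p = 0.113) and without a trend in the variance (adjusted p = 0.067).

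Red against dark gave 5750 called models, 3066 higher and 2684 lower (53.3% higher). With TPM 4978 were higher and 1463 lower (77.3%), and with median centring 2256 and 3499 (39.2%). At least 8-fold changes were called for 8 rises and 14 falls. In the authors' deposited table, 4158 of the tested models had q under 0.05, and 4127 of these were also called here.

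The third comparison tested the difference between the pulses. T-complex protein 11 (667321) stood at 1833 FPKM in blue and 4.73 FPKM in red libraries (log2 difference 8.32, adjusted p = 1.59e-10), aureochrome 4 at 1484 and 6.91 FPKM (7.55, adjusted p = 5.36e-09), and cryptochrome DASH at 129 and 0.53 FPKM (6.40, adjusted p = 8.1e-09). The desaturases 591536 and 606752 had log2 differences of 6.75 and 6.34. Lower in blue than in red libraries were a survival motor neuron model (591808, overlapping; 3.84 and 39.7 FPKM), a P-loop hydrolase of the DNA repair list (603275; 53.1 and 319 FPKM), a von Willebrand type A protein (588129; 4.37 and 30.7 FPKM), a methyltransferase (591027; 24.7 and 147 FPKM) and a BT1 family transporter (34886; 7.51 and 45.7 FPKM).

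Desaturases and elongases were higher in blue than in red libraries in 22 of 37 cases and lower in 7 (adjusted p = 0.000587), carotenoid genes in 11 and 2 of 19 (adjusted p = 0.0194), glycolysis genes in 23 and 6 of 38 (adjusted p = 0.00141), nitrogen assimilation in 13 and 2 of 21 (adjusted p = 0.0132), ribosomal proteins in 51 and 6 of 166 (adjusted p = 0.000587) and ribosome biogenesis in 58 and 10 of 115 (adjusted p = 0.000609), each with an adjusted p = 0.957 with an estimated correlation. Light harvesting genes were lower in 16 of 27 cases and higher in 5 (adjusted p = 0.00696). Lipases and beta oxidation genes were lower in 29 and higher in 8 of 74 (adjusted p = 0.00401). Both had an adjusted p = 0.957 with an estimated correlation. With fry, light harvesting (adjusted p = 0.36) and ribosomal proteins (adjusted p = 0.082) were not called between blue and red libraries. Adjusted over the list alone, the counts were 22 and 8 for desaturases, 11 and 3 for carotenoid genes, 14 and 2 for nitrogen, 47 and 5 for ribosomal proteins, 59 and 10 for ribosome biogenesis and 5 and 18 for light harvesting. Median, mean and test differed in sign for the proteasome (0.007, 0.006 and down), kinases (0.019, 0.049 and down), autophagy (0.002, −0.074 and down) and photoreceptors (−0.118, 0.946 and up). Within light harvesting, 581022 stood apart at 268.5 FPKM in blue and 5.91 FPKM in red libraries.

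Blue and red libraries differed in 4606 models, 2453 higher and 2153 lower in blue (53.3% higher). With TPM 1977 were higher and 2667 lower (42.6%), and with median centring 1898 and 2746 (40.9%). Across genes, which are not independent replicates, the changes after blue and red light correlated (Pearson's r = 0.762, Spearman's rho = 0.79). Unchanged groups simulated against the shared dark libraries gave r = 0.495. The covariance was 0.578 against 0.00843 in the simulation, a difference of 0.57. Both pulses raised 2526 models, where independent lists would share 1223, and lowered 2237, where they would share 972. With dark replicate 1 behind blue and dark replicate 2 behind red, a split made after seeing the data, r was 0.746. It gave 2009 models raised by both, where independent lists would share 883, and 1777 lowered, where they would share 695. With the dark libraries exchanged, r was 0.746 and the counts were 1989 against 862 and 1770 against 683. The calls of these splits still shared an estimate of variance. The dark libraries correlated at 0.9969 and are not stated to be separate cultures. The simulation drew its noise from the spread between replicates. Neither the simulation nor the splits can therefore account for a deviation that both dark libraries share. Of the models raised by both, 1187 were higher after blue and 140 higher after red light. Of those lowered by both, 843 were lower after blue and 179 lower after red light.

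**Figure D3:**
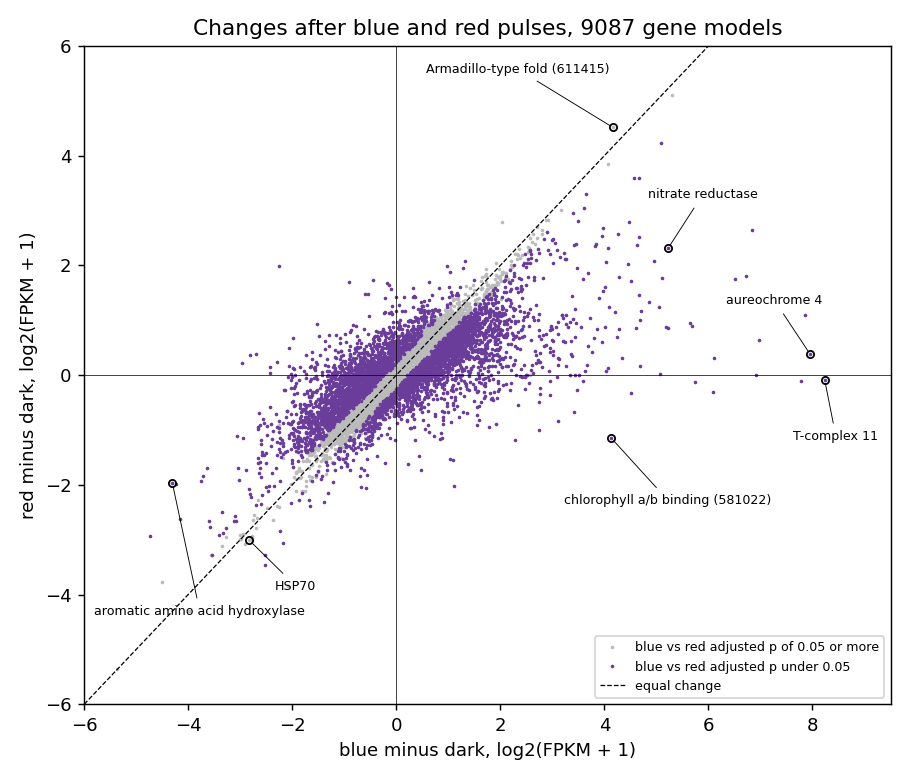
Change in log2(FPKM + 1) after red light (vertical axis) against that after blue light (horizontal axis), 1 point per model for 9087 models, with models whose blue and red libraries differed at adjusted p under 0.05 in purple and a dashed line of equal change. The rises of aureochrome 4 and T-complex protein 11 lie along the blue axis, with red changes of 0.39 and −0.09.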

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

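The tests between blue and red libraries were fixed before the data were examined, whereas the genes named here were chosen after their values were seen, as the 4 largest differences each way between blue and red libraries among models without overlap that changed in opposite directions. A first group of 138 models rose after blue and fell after red light, and 151 models fell after blue and rose after red light, each with a called difference between blue and red libraries. The called difference is no further support, because between opposite changes it is larger than either change. These counts follow the scaling: they were 65 and 305 with TPM, 134 and 137 with median centring, and 131 and 207 with quantile normalization.

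Among models that rose after blue light only, a chlorophyll a/b binding protein (581022) stood at 14.3 FPKM in dark, 269 FPKM in blue and 5.91 FPKM in red libraries, a blue minus red log2 difference of 5.28. A thioredoxin-like protein (579988) stood at 27.7, 190 and 13.5 FPKM in dark, blue and red (difference 3.73), an ankyrin repeat protein (63610) at 87.8, 691.5 and 68.5 FPKM (difference 3.31), and a mitochondrial carrier (582182) at 3.01, 12.9 and 1.09 FPKM (difference 2.71). In the other direction, a P-loop hydrolase (603275) stood at 225, 53.1 and 319 FPKM (difference −2.57), a methyltransferase (591027) at 124, 24.7 and 147 FPKM (difference −2.53), a WD40 repeat protein (674427) at 9.85, 2.94 and 16.9 FPKM (difference −2.22) and a cyclic nucleotide-binding-like protein (581981) at 17.2, 4.49 and 22.6 FPKM (difference −2.11). The call of the red change was lost for 4 of these 8 when 1 library was left out. For 63610 (log2 change −0.36) it was lost without dark replicate 1 (−0.367), dark replicate 2 (−0.344) or red replicate 1 (−0.29), and with TPM (−0.009). For 591027 (0.24) it was lost without dark replicate 1 (0.251), dark replicate 2 (0.236) or red replicate 2 (0.222), and with median centring (0.082). For 674427 (0.72) it was lost without red replicate 1 (0.622). For 581981 (0.37) it was lost without dark replicate 1 (0.294), red replicate 1 (0.284) or red replicate 2 (0.459), with quantile normalization (0.194) and median centring (0.21), and without a filter on low values (adjusted p = 0.0678).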

How the results depend on the processing

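The numbers of called models stayed within 1.5 times under all alternatives but a minimum change of 1 log2 (2588 in blue against dark, 1103 in red against dark, 879 in blue against red) and models without overlap, added after seeing the data (4317, 3629 and 2913, from 5654 models tested). Without 1 library each they ranged from 6055 to 6835, from 4621 to 6120 and from 3412 to 4739, the lone library being taken to vary like the other groups. The labels name no batch shared by libraries of the same replicate number. Deviations of same-numbered libraries correlated at 0.091 (dark and blue), −0.082 (dark and red) and 0.34 (blue and red). A factor shared by same-numbered blue and red libraries therefore stays open. A replicate block gave 7039, 5897 and 4858 called models. A block by the numbers in the library codes moved only red replicate 1, which then stood alone in its block. Red was therefore estimated from red replicate 2, much as when red replicate 1 is left out, so this is no second pairing. It gave 6939 called models in blue against dark. Under it 28 calls of named genes ended, among them 591027 (0.263) and 581981 (0.319) in red against dark. That of aureochrome 3 in blue against red ended too (−0.313). A count test was not run. Of the 22 lists, 8, 5 and 8 were called in the 3 comparisons; camera with an estimated correlation called 0, 0 and 0 (0 at an unadjusted p under 0.05), with a correlation estimated from 3 residual degrees of freedom, and fry, which does not compare a list with other genes, called 18, 12 and 10. The lists narrowed after seeing the data gave 8, 5 and 8. With TPM 2 lists were called in red against dark. Without 1 library the lists ranged from 8 to 9, from 4 to 5 and from 8 to 8, with ribosome biogenesis lost in red against dark without red replicate 2. The correlation of blue and red effects was 0.755 with TPM, 0.769 with a pseudocount of 5, 0.771 with a mean of at least 10 FPKM and 0.746 with a different dark library behind each pulse, both ways; over 8 choices of 1 library per group it ranged from 0.715 to 0.766. Of 8639 values of 156 named genes under alternatives, 8277 kept direction and call, 334 lost the call (124 through the minimum change) and 13 gained it. In blue against dark, log2 changes that turned sign were 0.028 (fatty acid hydroxylase 11480), 0.123 (elongase 592542) and 0.196 (desaturase 522533) with TPM; −0.193 (organic solute transporter 657968), −0.036 (GNS1/SUR4 672998), −0.141 (elongase 601182) and 0.534 (desaturase 522533) with quantile normalization; and −0.253 (657968), −0.115 (672998), −0.129 (601182) and −0.149 (oxidoreductase 602533) with median centring. Without 1 library 657968 ranged from −0.116 (blue replicate 1) to 0.140 (blue replicate 2), with −0.034 without dark replicate 2. In red against dark, aureochrome 3 (0.115) and desaturase 522533 (0.127) turned with quantile normalization. The genes that turned in blue against dark had no call there on FPKM, but 522533 was called as a rise with quantile normalization (adjusted p = 0.000835) and as a fall with median centring (−0.324, adjusted p = 0.0295), so its direction is open. Both genes that turned in red against dark had a call on FPKM; the cause was not tested.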

Other observations

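The tests of the functional classes and of neighbours with and without an annotation in common were chosen only after the result was seen. Of 22 functional classes of the deposited annotation, cytoskeleton models fell after blue light in 35 of 61 cases and rose in 11 (camera adjusted p = 0.0498, and adjusted p = 0.89 with an estimated correlation). This lies at the threshold. The class did not pass in red against dark (camera adjusted p = 0.152) or in blue against red (camera adjusted p = 0.17). Classes were tested on FPKM only, without other scalings or the removal of libraries. The class of translation, which contains the ribosomal proteins, rose in 234 of 314 cases and fell in 37 (adjusted p = 6.7e-11; adjusted p = 0.89 with an estimated correlation). Cyclins were among the rises of the cell cycle list, with 198387 up from 10.7 to 215 FPKM and a PHO80-like cyclin (667623) from 33.4 to 295 FPKM, while the chaperone Cdc37 (542225) fell from 258 to 41.5 FPKM. In the list of oxidative stress, a glutathione S-transferase (552717) rose from 7.02 to 233 FPKM and its neighbour, a thioredoxin-like protein (552718), from 1.84 to 35.9 FPKM.

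More genes rose than fell when each library was scaled to the same total, as in TPM. The 100 most abundant models took a larger share of the dark totals, and leaving them out lowered the median change after blue light from 0.282 to 0.162 on the log2 scale. This left 57.4% of the shift, between 47.6% and 61.2% over the 4 pairs of a blue and a dark library, around the threshold of 50% set beforehand, so it cannot be told apart whether abundant dark transcripts are its main source. A different amount of messenger RNA per cell stays open, since no value of RNA per cell was used here. The biological difference between pulsed and dark cells stays open as well.

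Of 12 models with a group mean below 0.01 FPKM in one group and of 10 FPKM or more in another, 11 overlap another model (91.7%, exact 95% interval 61.5% to 99.8%), against 37.8% of all tested models. This is consistent with reads being reassigned between overlapping models, and such models may not have changed at all. They include the Ysc84 domain model (573276) and the NUDIX hydrolase (574073). The exception, m55556, a model without a description, was listed at 0 in 4 libraries and at 1560 and 1182 FPKM in blue replicate 2 and red replicate 2.

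Adjacent genes responded alike to blue light, with r = 0.252 across 8967 adjacent pairs against at most 0.03 in 1000 random pairings. Overlapping models do not account for all of it, as r was 0.209 over 7238 pairs without overlap. Overlap was judged by the annotated coordinates, so reads running past annotated ends were not tested. Adjacent copies of a family may be part of it. Leaving out pairs of the same description removed few pairs (r = 0.207 over 7200). The 125 annotated pairs with an annotation in common had r = 0.847, and 3590 annotated pairs with none in common 0.159 (random at most 0.055). Copies that share an annotation are thus not the whole source. An annotation in common meant an identical line, so copies worded differently stay open, as do models without annotation. A candidate explanation for another part is a shared upstream region: divergent pairs had r = 0.328, pairs in tandem 0.213 (random at most 0.083) and convergent pairs 0.074, with a difference of 0.116 between the first and second kind (95% interval 0.058 to 0.178 over resampled scaffolds). An example is the aromatic amino acid hydroxylase 585185 and the neighbouring 585179, which are transcribed away from each other and both fell after blue light.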
